A study of Saccharomyces cerevisiae with 23 samples.

How the data were processed

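The 23 samples were arrays with 2 channels, each with total RNA of 1 yeast culture in 1 channel and a reference pool of BY4716 RNA in the other, per the labels. The labels call the cultures independent, and name them 1, 2, 3, A, B and C in each strain. The deposited values are taken as log2 ratios of the channels, 1 per probe and array. The base of the logarithm is not given in the sources used here. It was taken as 2, because the largest deposited value, 13.42, would exceed the range of a 16-bit scanner as a natural logarithm. If the base were another, every size would scale with it, and calls would not change. The mean of each deposited array is 0 within rounding, so the authors centred them; dyes, background correction, normalization and the filter on missing values are not given in the sources used here. Medians of the deposited arrays lay between -0.039 and 0.042. No spot intensities were used here.

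The direction of the ratios is not given in the sources used here. Wild strain arrays of opposite orientation correlated positively across genes (r from 0.72 to 0.88), so the deposited columns already ran the same way and no array was turned on its own, although the plan had foreseen turning them by orientation. Whether the labels of orientation are right cannot be told from this. LYS2 was negative on all 11 wild strain arrays as deposited, LEU2 positive on all 11 and URA3 positive on all 9 with a value. By the rule set for these 3 markers all values were multiplied by -1, giving culture over pool as the likely direction. BY4716 arrays of the same orientation correlated at r from 0.19 to 0.84, and of opposite orientation from -0.38 to 0.62.

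Of 7085 rows, 502 had no value, 5645 probes had 1 gene in the platform annotation, none had several, and 938 probes with values had no listed gene. Names were updated through the R64 gene table, which was also used for which genes neighbour each other; as the platform's build is not named, no coordinates are printed. Probes of a gene were averaged, giving 5605 genes. Of these, 40 had 2 or more probes, 15 of them were called, and MOB2 and PYC2 were called with probes on opposite sides of 0. Number of columns left unused: 0.

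Each array was centred on its median, and the arrays of a culture were averaged, so that the culture is the replicate. Genes with values in at least 4 of 6 cultures of each strain were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, in 1 fit of the 12 cultures with strain as the only term, and called at a Benjamini-Hochberg adjusted p under 0.05. The same fit tested each strain's mean against the pool. The channel effect was the difference between a culture's orientations, divided evenly between them, tested against 0 in genes with at least 8 cultures. All adjusted p-values are from limma. The 39 gene lists were tested with camera at a preset correlation of 0.01 on the 4356 genes complete in 12 cultures, for the 35 lists with at least 4 such members. With the preset correlation 25 lists passed, 14 higher and 11 lower. With an estimated correlation 5 did (alpha-specific, a-specific, daughter cell separation, respiratory chain and Y' helicases). For the purine list the estimated correlation, 0.013, was near the preset one, yet its camera adjusted p went from 0.0281 to 0.167. The loss of lists thus cannot be put down to correlated members alone. None of the mitochondrially encoded genes was measured.

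The groups, tests, gene lists, alternatives and the rule for named genes were set before the data were examined. The rule takes the 12 largest rises and 12 largest falls among called genes whose cultures do not overlap between strains, with at most 2 of near-identical copies of a family, in each list up to 4 members with the smallest adjusted p, the 3 direction markers, and the 5 largest called changes of BY4716 against the pool. Which genes form the families of near-identical copies was written after the data were seen. The alternatives were no centring, scaling to 1 median absolute deviation, quantile normalization, other rules for missing values, removal of the channel effect, single orientations, every array with culture as a random block, robust eBayes, array weights, the culture set or name as a block, subsets of cultures, a size threshold of 1.5-fold, an exact rank-sum test, and leaving out each culture in turn. Others, added after seeing the data, concerned probes with no gene name, cultures with both orientations, lettered or numbered BY4716 cultures only, repeated families, all tested genes in camera, and list counts by scaling and without wild strain culture 1.

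The fit was tested on simulated data with the spread and missing values of the 5418 tested genes and 200 changed genes. It recovered 68% of changes of 0.5 in log2, 92% of changes of 1 and 100% of changes of 2 and of 4, with 10 false calls among 190. A simulated shift of 0.5 in the ergosterol list was called, with 0 other lists of 35. Genes were drawn independently there, so this cannot show how often lists of correlated genes are called falsely.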

Results

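Transcript levels were measured in the budding yeast Saccharomyces cerevisiae on 23 hybridisations to arrays with 2 channels. The laboratory strain BY4716, isogenic to the reference strain S288c, was set against a wild isolate from a vineyard. There were 12 independent cultures, 6 of each strain, each hybridised against a common reference pool of BY4716 RNA. All 6 BY4716 cultures and 5 of the 6 wild strain cultures were measured in both channel orientations. Wild strain culture 1 was measured once, with the culture in channel 2. Arrays held values for 4476 to 6181 probes, and the number of arrays limits the precision. Values below are log2 differences, wild strain minus BY4716 cultures, with their standard errors (SE) and n = 6 cultures per strain unless given otherwise. There were 5 BY4716 cultures for GIT1 and ADH1, and 5 wild strain cultures for GRE1, TKL2, SUL2 and ADA2. The direction is likely rather than stated, and rests on 3 marker genes described below.

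Among the larger differences were those of mating type genes, repeated or clustered genes, daughter cell separation genes, respiratory chain genes and single biosynthetic genes such as LEU1. With arrays centred on their medians, the pheromone receptor gene STE2 had the largest rise, 6.39 ± 0.18 (adjusted p = 1.35e-11), and the asparaginase gene ASP3-2 the largest fall, -7.83 ± 0.55 (adjusted p = 1.09e-07). The order depends on the processing: under quantile normalization the Ty gene YML040W was at -5.21 and ASP3-2 at -4.41. Signals at background were not told apart here, so the largest sizes may be bounds rather than folds. Of 5418 genes tested with limma, 2418 passed an adjusted p of 0.05, or 44.6%. Of these, 1332 were higher and 1086 lower in the wild strain, with a median absolute change of 0.45. A change of at least 2-fold was seen for 399 called genes, 214 higher and 185 lower. At 16-fold or more, 6 were higher and 25 lower. The values of the strains did not overlap for 1313 called genes. Of these, 1046 had values for 6 cultures of each strain, where chance gives a share of 0.00216 of genes, and 267 had fewer, with a share of up to 0.0286. Scaling every array to the same spread lowered the number of calls to 1359, and quantile normalization to 1270. Without wild strain culture 1, whose ratios had a narrower distribution than those of the other wild strain arrays, 2573 genes were called.

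**Figure D1:**
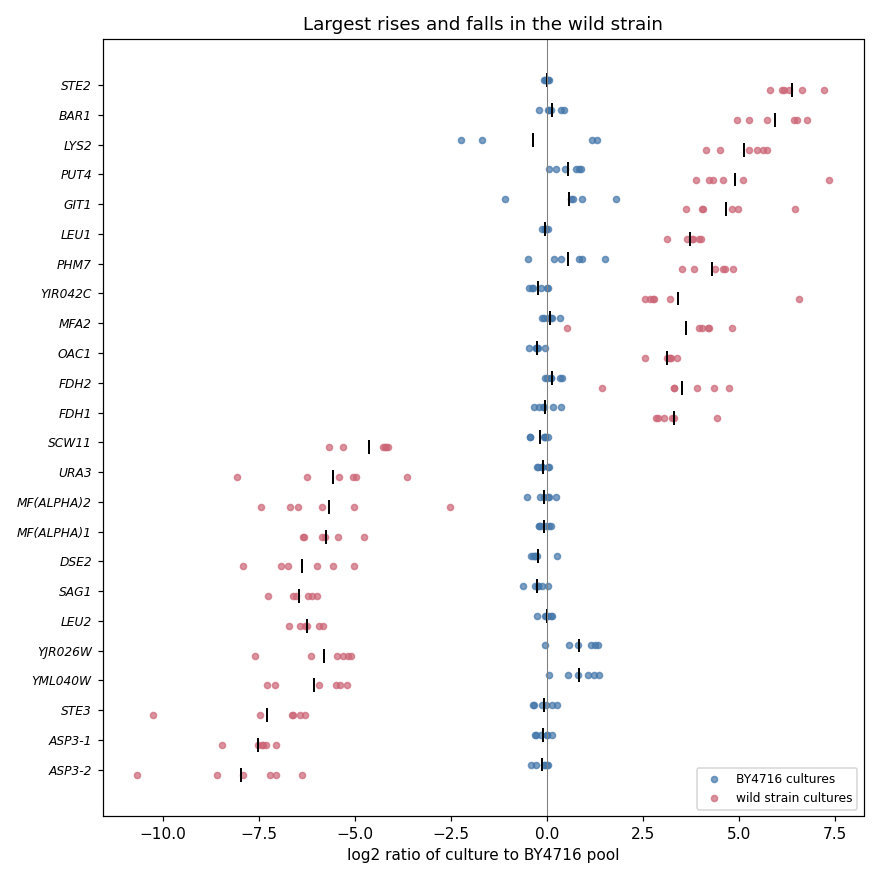
Each point is the log2 ratio of 1 culture to the BY4716 pool (horizontal axis) for the 12 largest rises and 12 largest falls named by the rule for named genes; black bars are strain means. The wild strain values lie apart from the BY4716 values for every gene shown, with STE2 highest at a wild strain mean of 6.37 and ASP3-2 lowest at -7.97.

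All tested genes specific to one mating type were called, with 5 of the 7 fixed a-specific genes tested. All 5 a-specific genes tested were higher in the wild strain (5 adjusted over the list alone), with a median of 4.32, or 2.74 under quantile normalization. In MFA1, named after its values were seen, the cultures of the strains overlapped. STE2 encodes the alpha-factor receptor, and BAR1, the protease that degrades alpha-factor, rose by 5.81 ± 0.28. The a-factor gene MFA2 was higher by 3.55 ± 0.55, with wild strain culture 1 at only 0.52 above the pool, and its transporter gene STE6 by 3.06 ± 0.20. All 4 alpha-specific genes were lower (4 adjusted over the list alone), with a median of -5.94, or -3.42 under quantile normalization. They were the a-factor receptor gene STE3 at -7.20 ± 0.55, the agglutinin gene SAG1 at -6.19 ± 0.19, and the alpha-factor genes MF(ALPHA)1 at -5.68 ± 0.22 and MF(ALPHA)2 at -5.59 ± 0.63. Both lists passed with an estimated correlation (adjusted p = 0.0179 for each). Of 18 pheromone response genes 11 were lower and 1 higher (14 and 2 adjusted over the list alone). The agglutinin anchor gene AGA1 was at -2.66 ± 0.12 and the desensitisation gene SST2 at -1.21 ± 0.12, while the transcription factor gene TEC1 rose by 0.95 ± 0.09. That list's shift had an adjusted p = 0.00801, and adjusted p = 0.285 with an estimated correlation. Among 9 haploid-specific genes, 3 were higher and 2 lower (3 and 2 adjusted over the list alone). The endonuclease gene HO was at -4.23 ± 0.24 and the kinase gene FUS3 at 0.55 ± 0.10. Whether HO is absent or altered in the wild strain, rather than less transcribed, was not tested. The list's median was 0.10, its mean -0.38, and its test ran upward with an adjusted p = 0.894.

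A set of 3 marker genes fixed the direction of the ratios. LEU2, of leucine biosynthesis, was at -6.24 ± 0.13, and URA3, of pyrimidine biosynthesis, at -5.45 ± 0.53. LYS2, of lysine biosynthesis, was higher by 5.49 ± 0.68, with values for 4 BY4716 cultures only, which ran from -2.23 to 1.29, and its adjusted p of 6.58e-05 did not hold under quantile normalization (3.76, adjusted p = 0.103). BY4716 is known to lack LYS2 and to be of mating type alpha, and the vineyard parent of this cross is known to carry leu2 and ura3 mutations and to be of mating type a. For LYS2 neither the BY4716 cultures nor the BY4716 pool should then rise above background, so its size is not a measured fold and only its sign was used. For LEU2 and URA3 the wild strain signal may likewise be at background, so their sizes may be bounds rather than folds. Across the alternatives LEU2 and URA3 were as small as -3.54 and -3.05. The same limit may hold for the a-specific genes, where the BY4716 cultures and pool may be at background. It may hold as well for the alpha-specific genes and the ASP3 copies, where the wild strain signal may be at background. The mating type lists were not used to set the direction.

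Several lists of biosynthetic genes held many genes called higher, though none of those below passed with an estimated correlation. Of 12 genes of leucine and branched-chain amino acid synthesis, 9 were higher and none lower (9 adjusted over the list alone). LEU1, the isopropylmalate isomerase gene, rose by 3.76 ± 0.12, the mitochondrial carrier gene OAC1 by 3.37 ± 0.12 and the transaminase gene BAT1 by 2.52 ± 0.14. The list passed at an adjusted p = 4.41e-05, and gave adjusted p = 0.32 with an estimated correlation. Of 11 pyrimidine genes, 4 were higher and 2 lower (4 and 2 adjusted over the list alone). The dihydroorotate dehydrogenase gene URA1 rose by 2.93 ± 0.13, URA10 by 3.16 ± 0.42 and URA4 by 1.38 ± 0.09. However, the list's median was 0.01 and its adjusted p was 0.203. It passed under quantile normalization (0.0176) and in camera on the limma t values of all tested genes (0.0348). Of 8 lysine genes, 5 were higher (6 adjusted over the list alone). LYS1 rose by 1.58 ± 0.29 and LYS21 by 0.83 ± 0.14, and the list had an adjusted p = 0.0281, or adjusted p = 0.518 with an estimated correlation. Without wild strain culture 2 the lysine list no longer passed (adjusted p = 0.0533). Nor did it in camera on the limma t values of all tested genes (adjusted p = 0.134). Arginine genes were higher for 7 of 9 (7 adjusted over the list alone), with ARG4 at 1.89 ± 0.30 and the ornithine transaminase gene CAR2 at 1.48 ± 0.17. CAR2 was not called under quantile normalization (0.39, adjusted p = 0.183). Histidine genes were higher for 5 of 7 (5 adjusted over the list alone), with HIS4 at 1.78 ± 0.27 and HIS5 at 1.65 ± 0.19. Sulfur assimilation and methionine genes were higher for 17 of 24 and lower for 1 (17 and 1 adjusted over the list alone), with MET13 at 1.82 ± 0.17 and the sulfate permease gene SUL2 at 1.17 ± 0.16. With an estimated correlation these lists had adjusted p = 0.401 for arginine, adjusted p = 0.395 for histidine and adjusted p = 0.285 for sulfur. Under quantile normalization the arginine list no longer passed (adjusted p = 0.207), with 2 genes higher and a median of 0.65, against 1.32 with centring alone and 0.71 with arrays scaled to the same spread. In cultures 1 to 3 alone MFA2, LYS1, LYS21, ARG4 and HIS4 were not called (adjusted p from 0.0572 to 0.0983), at 3.09, 1.57, 0.72, 1.60 and 1.65.

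Respiratory and sterol genes were also higher. All 32 nuclear genes tested of the respiratory chain were called higher (32 adjusted over the list alone), with a median of 1.23. With arrays scaled to the same spread 30 were (median 0.82), and under quantile normalization 30 (median 0.72). The Rieske protein gene RIP1 rose by 2.02 ± 0.08, the cytochrome oxidase subunit gene COX5A by 1.84 ± 0.05 and the succinate dehydrogenase gene SDH1 by 1.65 ± 0.08. This list passed with an estimated correlation too (adjusted p = 0.0272). Of 14 tricarboxylic acid cycle genes, 10 were higher (11 adjusted over the list alone), with an adjusted p = 4.41e-05 and adjusted p = 0.167 with an estimated correlation. With arrays scaled to the same spread 4 were higher (median 0.17), and under quantile normalization 3 (median 0.13), against a median of 0.41 with centring alone. The malate dehydrogenase genes MDH2 and MDH1 were at 2.41 ± 0.10 and 0.59 ± 0.09. MDH1 was not called with arrays scaled to the same spread (0.24, adjusted p = 0.154) or quantile normalized (0.13, adjusted p = 0.447). Of 23 ergosterol genes, 19 were higher and 1 lower (20 and 1 adjusted over the list alone), among them ERG11 at 1.13 ± 0.10 and ERG5 at 1.09 ± 0.10; the list gave adjusted p = 4.15e-08 and adjusted p = 0.0502 with an estimated correlation. Heme- and oxygen-responsive genes were higher for 8 of 13 and lower for 3 (8 and 4 adjusted over the list alone). In that list the catalase gene CTT1 was at 2.90 ± 0.13, the flavohemoglobin gene YHB1 at 2.14 ± 0.11 and the cytochrome genes CYC7 and CYT1 at 1.85 ± 0.11 and 1.72 ± 0.08. Its adjusted p was 0.0304, with adjusted p = 0.194 with an estimated correlation and 0.173 under quantile normalization. Glycolysis and fermentation genes were lower for 11 of 20 (12 adjusted over the list alone), with the alcohol dehydrogenase genes ADH2 at -1.13 ± 0.16 and ADH1 at -0.95 ± 0.13 and the hexokinase gene HXK2 at -0.96 ± 0.12. This list gave adjusted p = 0.000236 and adjusted p = 0.263 with an estimated correlation, and ADH2 was not called under quantile normalization (-0.89, adjusted p = 0.0838).

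Daughter cell separation genes were lower in the wild strain for 9 of 12 (9 adjusted over the list alone), with a median of -1.30. The secreted glucanase-related genes DSE2 and SCW11 were at -6.13 ± 0.38 and -4.45 ± 0.25, DSE1 at -4.07 ± 0.07 and SUN4 at -2.42 ± 0.10. Across the alternatives DSE2 ran from -6.82 to -3.38 and SCW11 from -4.80 to -2.44. With arrays scaled to the same spread 9 genes of the list were lower (median -0.95), and under quantile normalization 9 (median -0.87). The list passed with both the preset and the estimated correlation (adjusted p = 1.16e-09 and 0.0179).

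Ribosomal, chaperone and stress genes moved in both directions. Of 131 cytosolic ribosomal protein genes, 75 were lower and 1 higher (85 and 1 adjusted over the list alone), with a median of -0.30 and, for example, RPL7B at -1.26 ± 0.17. Without wild strain culture 1, 105 of 130 were lower. With every array scaled to the same spread only 12 were, and removing the channel effect left 35. The list had an adjusted p = 6.22e-12, and adjusted p = 0.411 with an estimated correlation. Mitochondrial ribosomal protein genes were higher for 30 of 69 and lower for 1 (30 and 1 adjusted over the list alone), with MRPL38 at 0.80 ± 0.10; the list gave adjusted p = 0.00011 and adjusted p = 0.547 with an estimated correlation, and 11 and 12 genes were higher with arrays scaled to the same spread and quantile normalized. Of 24 heat shock and chaperone genes, 16 were lower and 2 higher (16 and 2 adjusted over the list alone). The small heat shock gene HSP26 was at -3.13 ± 0.19, the Hsp70 genes SSA2 and SSA1 at -1.20 ± 0.12 and -1.16 ± 0.10, and the disaggregase gene HSP104 at -1.13 ± 0.10. That list gave adjusted p = 5.5e-05 and adjusted p = 0.194 with an estimated correlation. General stress genes were higher for 16 of 30 and lower for 1 (18 and 1 adjusted over the list alone), with GRE1 at 3.27 ± 0.27 and the transketolase gene TKL2 at 2.29 ± 0.21. Their median of 0.43 flipped to -0.02 with arrays scaled to the same spread and to -0.15 under quantile normalization. Of 50 ribosome biogenesis genes, 12 were lower (4 adjusted over the list alone), with a median of -0.22 that flipped to 0.02 and 0.23 under the same settings. The direction of both lists thus depends on the scaling. Both settings stretch the narrow BY4716 arrays by construction, so the flips alone cannot decide it. With the channel effect removed the medians were 0.45 for general stress and -0.22 for ribosome biogenesis. Without wild strain culture 1 they were 0.42 and -0.29. With an estimated correlation these lists had adjusted p = 0.401 for general stress and adjusted p = 0.663 for ribosome biogenesis.

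Repeated and clustered genes gave many of the deepest falls. All 4 copies of ASP3, which encode a cell wall asparaginase, were lower (4 adjusted over the list alone), with ASP3-1 at -7.42 ± 0.19 and a median of -7.38, or -4.24 under quantile normalization. Their list gave adjusted p = 2.15e-06 and adjusted p = 0.0564 with an estimated correlation. All 3 sodium pump genes were lower (3 adjusted over the list alone), with ENA5 at -3.11 ± 0.16, ENA1 at -3.04 ± 0.18 and ENA2 at -2.64 ± 0.15. All 7 helicase genes of the subtelomeric Y' element were lower (7 adjusted over the list alone), among them YRF1-6 at -2.40 ± 0.08 and YRF1-7 at -2.34 ± 0.07, and their list passed with an estimated correlation (adjusted p = 0.0483). Of 26 Ty retrotransposon genes, 24 were lower, with YML040W at -6.91 ± 0.37 and YJR026W at -6.64 ± 0.39. The other 2, named after their values were seen, were YCL020W and YBL100W-A, both higher. Near-identical copies share hybridisation signal, so single copies of these families are uncertain. The counts of these families, and the list tests of ASP3 and the Y' helicases, may thus count 1 signal several times. The remaining large rises were the proline permease gene PUT4 at 4.37 ± 0.47, the glycerophosphoinositol permease gene GIT1 at 4.07 ± 0.54, PHM7 at 3.74 ± 0.31, YIR042C at 3.65 ± 0.56, with wild strain culture 3 far above the others, and the formate dehydrogenase genes FDH2 and FDH1 at 3.37 ± 0.42 and 3.34 ± 0.23. GIT1 was not called under quantile normalization (1.72, adjusted p = 0.191). The lowest values across the alternatives were 2.47 for PUT4, 1.94 for PHM7 and 2.1 for FDH2. For PUT4, wild strain culture 1 was at 7.34, against a mean of 4.42 for the others. FDH2 and FDH1 are near-identical, so their separate values are uncertain.

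**Figure D2:**
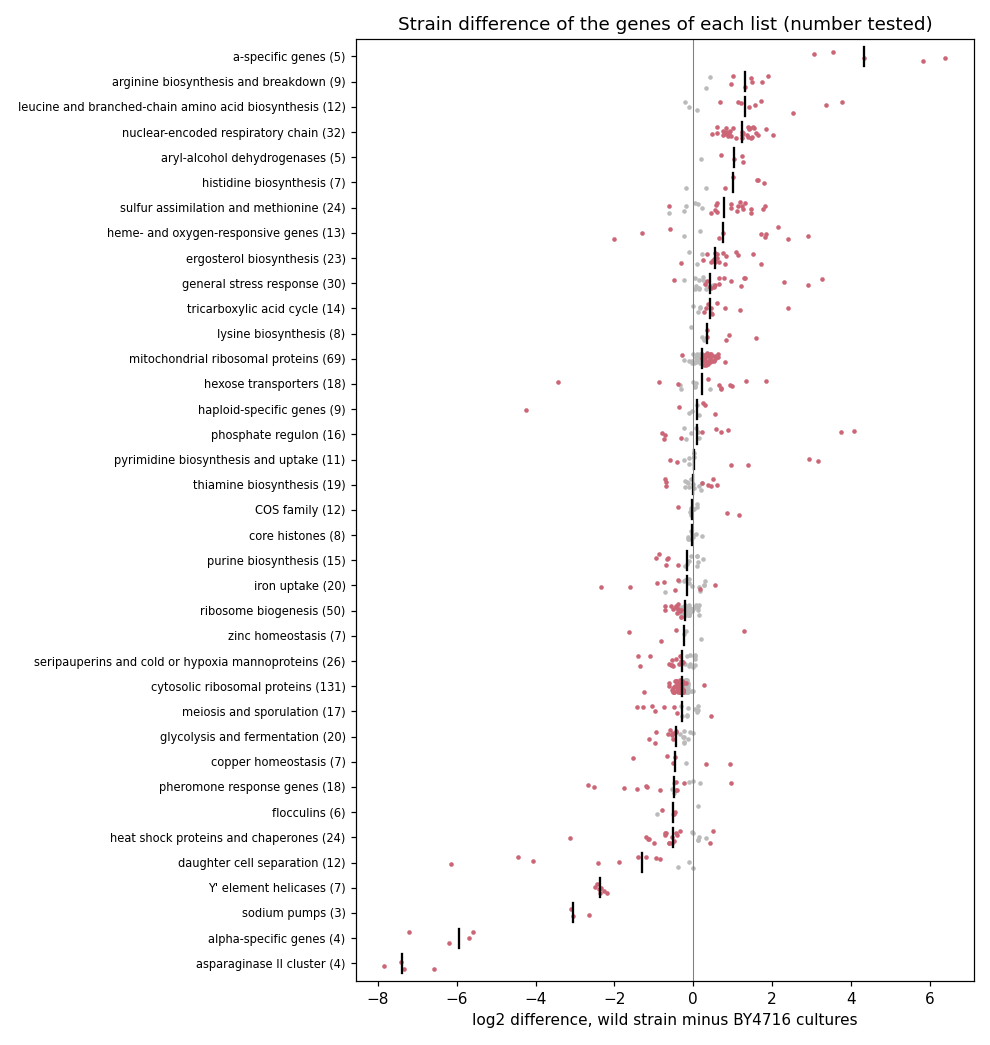
Each point is the log2 difference, wild strain minus BY4716 cultures (horizontal axis), of 1 gene of the named list; coloured points passed an adjusted p of 0.05, grey points did not, and black bars are list medians. List medians run from -7.38 for the asparaginase cluster to 4.32 for a-specific genes; those of general stress and ribosome biogenesis genes flip in sign when arrays are scaled to the same spread.

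The BY4716 cultures were then set against the BY4716 pool, a comparison of the strain with itself. It holds differences between the cultures and the pool as well as the background of the measurement. Its residual spread came from the fit of all 12 cultures, so the spread of the wild strain cultures entered its p-values. Differences were small: 643 of 5466 genes were called, 345 higher and 298 lower than the pool, with a median absolute change of 0.29. Only 3 reached 2-fold, the Y' element reading frames YBL111C at 1.24 ± 0.35 (adjusted p = 0.0384), YHR218W at 1.20 ± 0.33 (adjusted p = 0.0321) and YBL112C at 1.07 ± 0.27 (adjusted p = 0.0252). None of the 3 reached 2-fold in a lettered culture: YBL111C was at 1.66 to 2.39 in the numbered and 0.46 to 0.67 in the lettered ones, YHR218W at 1.67 to 1.90 and 0.42 to 0.72, and YBL112C at 0.62 to 2.35 and 0.48 to 0.93. The catalase gene CTT1 was higher by 0.97 ± 0.09 and the transcriptional coactivator gene ADA2 by 0.94 ± 0.11. General stress genes were higher than the pool for 22 of 30 (27 adjusted over the list alone), with a median of 0.53. Heat shock genes were higher for 12 of 24 (13 adjusted over the list alone), and ribosome biogenesis genes lower for 19 of 50 (28 adjusted over the list alone), with a median of -0.32. Heat shock genes had a median of 0.24. Scaling to the same spread and quantile normalization kept the sign of these 3 medians but moved their sizes, under quantile normalization to 0.92 for general stress, 0.39 for heat shock and -0.58 for ribosome biogenesis, with 30 ribosome biogenesis genes lower. The count of calls depended on single cultures: it was 326, 247, 328 and 415 without BY4716 cultures 1, 2, 3 and A. Without wild strain culture 1 it was 869. Across all settings it ran from 16 with only the lettered BY4716 cultures to 1717 under quantile normalization. The pool is 1 sample, so its own spread is left out of this test.

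**Figure D3:**
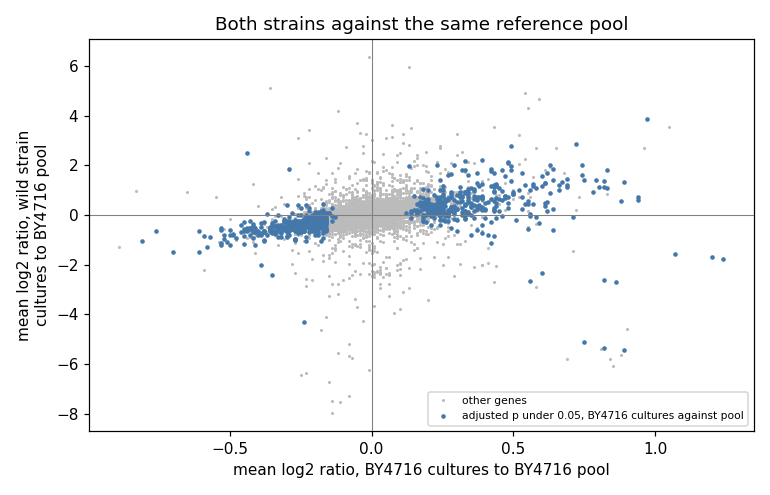
Each point is 1 gene, with the mean log2 ratio to the BY4716 pool of the BY4716 cultures (horizontal axis) and of the wild strain cultures (vertical axis); blue points passed an adjusted p of 0.05 for BY4716 against the pool. Of these called genes, 86.6% had their wild strain mean on the same side of the pool.

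The wild strain cultures against the same pool gave 3692 called genes of 5454, 1889 higher and 1803 lower, with a median absolute change of 0.41, and 490 of at least 2-fold. The spread of the pool is left out of this test too. In 20 simulations no culture changed and the pool varied like 1 more culture. A median of 1629 genes was then called for the wild strain against the pool. A pool may vary less than 1 culture, so this number may be too high. CTT1 was 3.88 above the pool in the wild strain (SD 0.10), against 0.97 (SD 0.34) in BY4716, while HSP26 was at -2.71 (SD 0.32) against 0.43 (SD 0.40). AGA2, the a-agglutinin subunit gene, had values for 1 BY4716 culture only and so was not tested between strains. It was at 3.95 (SD 1.24, n = 6) in the wild strain, and is named after its values were seen. Only the cultures with both orientations and genes with a value on every array gave 2370 calls among 3214 genes.

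The channel that held the culture moved many probes slightly. Over the 11 cultures with both orientations, 2522 of 4616 genes had a channel effect past the threshold, 929 positive and 1593 negative. Its median size was 0.094, its 95th percentile 0.29 and its highest value 1.12, so it lay far below the differences of STE2, ASP3-1 or LEU1. For a gene with values on both arrays of a culture the effect cancels in their mean. It does not cancel for a gene with a value in 1 orientation only, or in wild strain culture 1. With it removed, 2318 genes were called between the strains.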

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

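The tests on wild strain culture 1, the simulation of the pool and the test on genes called in the numbered cultures alone were chosen only after the result was seen; the tests on other groupings and on the side of the pool were set before. Among 320 groups of 6 or fewer culture values of named genes, 23 held a culture far from the others, 11 of them wild strain culture 1; chance flags about 5% of groups. In wild strain culture 1 the log2 ratios to the pool were 7.34 for PUT4 (mean of the others 4.42), 0.52 for MFA2 (4.24), 2.55 for OAC1 (3.23), -10.26 for STE3 (-6.69), 1.79 for BAT1 (2.64), 1.64 for URA4 (1.15), 0.70 for URA2 (1.05), -0.03 for LYS21 (0.83), 0.68 for ERG5 (1.14), -0.32 for ZPS1 (-2.58) and 0.24 for THI7 (0.78). In wild strain culture 3 they were 6.55 for YIR042C (2.80), 1.54 for ARG2 (0.75) and 1.40 for AAD14 (1.04). In wild strain culture C they were 4.42 for FDH1 (3.07) and -8.46 for ASP3-1 (-7.34), in culture A 1.04 for IDH1 (0.81) and -0.20 for CTR1 (-0.91), and in culture 2 -0.27 for PAU12 (-0.49). Among BY4716 cultures, DSE2 was at 0.26 in culture 1 (-0.33), ERG9 at 0.33 in culture A (0.10), PGI1 at 0.01 in culture C (0.19) and GRE1 at -1.29 in culture 3 (0.23).

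The array of wild strain culture 1 had an interquartile range of 0.40, against 0.55 to 0.79 for the other wild strain arrays. BY4716 RNA mixed into the sample would bound every fall, yet the slope of this culture on the other wild strain cultures was higher by 0.39 (SE 0.066) for genes over 4 units lower than for genes changed by 0.5 to 1 unit. Its single orientation does not account for it, since the lowest range among the other wild strain arrays with the culture in channel 2 was 0.68. A single scaling factor would give 1 slope for all genes. Genes changed by more than 2 units had a slope higher by 0.25 (SE 0.039) than genes changed by 0.5 to 1 unit. Genes were grouped by the mean of the other cultures, whose noise may lower the slope among small changes. No other wild strain culture was examined in this way, so scaling is not excluded. For the mixing, the slope of 1.06 (SE 0.064) among genes over 4 units lower does not rest on small changes. The array also held values for 5443 probes but only 4633 genes, against 5322 probes and 4857 genes for wild strain culture C in channel 2. The cause of that was not tested. A difference in growth of culture 1, or a compression of small ratios on its array, was not tested and could account for the narrow range.

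The BY4716 cultures differed from their own pool in 643 genes, and 1 of 32 choices of sign for the cultures gave as many, with 2 genes at most for the others; this excludes chance between the cultures, not a chance deviation of the 1 pool they share. Of the called genes 86.6% (95% exact binomial interval 83.7 to 89.1%, which treats genes as independent) had their wild strain mean on the same side, consistent with a pool that itself deviates. With no change in any culture and a pool that varies like 1 more culture, 20 simulations called 1590 to 1781 genes, with 98.1% on the same side. The observed count lay below every simulated one, and the simulated share on the same side lay above the interval of the observed share. A pool may vary less than 1 culture, so the simulated pool may deviate too much. A deviating pool would also shift lettered and numbered cultures alike, yet the lettered BY4716 cultures alone gave 16 calls, against 545. The simulation thus neither shows nor excludes that the pool accounts for the difference between the BY4716 cultures and the pool. Whether the numbered cultures alone account for it stays open: the called genes moved in the lettered cultures by a median of 0.62 times that in the numbered ones, but were chosen on both, and the 545 genes called in the numbered cultures alone moved by 0.32 times (medians of 0.07 to 0.27 in single lettered cultures).

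Between the strains, 1 of 100 splits of the 12 cultures called as many genes as the real 2418, and the highest other called 89. For lists, 1 of 100 gave the real 25, but the highest other gave 22; the cause of that was not tested. For the channel effect 1 of 96 choices of sign gave the real 2522, and the highest other gave 964. Chance can be excluded for the counts of genes and of channel effects, and by the same rule for the 25 lists. As another split gave 22 lists, this does not show that so many lists differ by strain. Over both strains, 51 genes differed between lettered and numbered cultures by limma, 15 higher and 36 lower in the lettered ones. The strain difference itself differed between lettered and numbered cultures for 1 gene by an interaction term in limma (524 at an unadjusted p under 0.05), SNO1, at 3.96 in numbered and 1.54 in lettered cultures (difference -2.41, adjusted p = 0.00217). As 27 of 100 groupings, the real one included, called as many, up to 245, chance cannot be excluded there. Among 599 tested probes with no listed gene, 214 differed between the strains, 51 higher and 163 lower.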

How the results depend on the processing

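Of 4641 values of named genes recomputed across the alternatives, 4550 kept their direction and side of the threshold, 77 no longer passed, 10 newly passed and 4 reversed: DBP2 (0.39), DBP8 (0.1), YTM1 (0.14) and ZPS1 (0.12), all under quantile normalization. The list tests of ribosome biogenesis (adjusted p = 0.347) and general stress (adjusted p = 0.0369) reversed there. Scaling to 1 median absolute deviation and quantile normalization stretch the narrow BY4716 arrays by construction: they gave 1359 and 1270 calls between strains and 1588 and 1717 for BY4716 against the pool. For that last comparison, every array with a random block gave 1040, channel 2 alone 1101, channel 1 alone 1172, array weights 1248, cultures A to C 273, and lettered and numbered BY4716 cultures alone, chosen after seeing the data, 16 and 545; the cause was not tested. Cultures 1 to 3 gave 679 calls between strains, 195 for BY4716 and 2134 for the wild strain against the pool, where A to C gave 2511, 273 and 3592; the cause was not tested. A change of at least 1.5-fold left 854, 54 and 1135. Cultures with both orientations and genes on every array, chosen after seeing the data, gave 2370 of 3214 for the wild strain against the pool; the cause was not tested. The exact rank-sum test gave 1518 at p under 0.005, where 22.9 are expected by chance. An estimated correlation left 5 lists. Leaving out each culture gave 2162 to 2573 calls between strains, 247 to 869 for BY4716 and 3432 to 3702 for the wild strain against the pool, 24 or 25 lists, and 2201 to 2488 genes with a channel effect. Culture names shared between strains were not taken to pair the cultures, since only 4 of 6 correlations of deviations were over 0.1 (-0.23 to 0.42), although 4 of 6 were best with their own name, a hint from the data, not the design; the replicate block gave 2394 calls and 25 lists. The number of arrays, not signal over background, which was not used here, is the limit that could be examined.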

Other observations

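The tests on neighbouring genes, on chromosome ends and on pathways around the marker genes, the list test on t values and the list counts by scaling were chosen only after the result was seen. There were 5 wild strain cultures for HXT13, CTR3, FLO9 and IME1. Nutrient genes moved in both directions. Of 18 hexose transporter genes, 8 were higher and 3 lower in the wild strain (8 and 3 adjusted over the list alone): GAL2 rose by 1.83 ± 0.23 and HXT2 by 1.33 ± 0.20, while HXT13 was at -3.42 ± 0.24. With arrays scaled to the same spread 3 were higher and 2 lower, and under quantile normalization 4 and 1. That list passed upward on its 9 genes with complete values (adjusted p = 0.0194). It did not pass in camera on the limma t values of all tested genes (adjusted p = 0.632) or with an estimated correlation (adjusted p = 0.404). Without wild strain culture 1 (0.159) or 3 (0.054) it did not pass either. Of 16 phosphate genes, 6 were higher and 4 lower (6 and 4 adjusted over the list alone), with the acid phosphatase gene PHO5 at -0.75 ± 0.09 and VTC3 at 0.87 ± 0.12. PHO5 was not called under quantile normalization (-0.30, adjusted p = 0.158). Of 20 iron genes, 2 were higher and 6 lower (2 and 6 adjusted over the list alone), with the siderophore transporter gene ARN2 at -2.35 ± 0.29 and FET4 at -1.61 ± 0.16. With arrays scaled to the same spread none was higher and 4 lower, and under quantile normalization none and 2, with FET4 not called (-0.37, adjusted p = 0.382). Of 7 zinc genes, 1 was higher and 3 lower (1 and 3 adjusted over the list alone), with the transporter gene ZRT1 at -0.81 ± 0.13, and the list median of -0.24 flipped to 0.08 under quantile normalization. ZRT1 was not called with arrays scaled to the same spread (-0.46, adjusted p = 0.0711) or quantile normalized (-0.13, adjusted p = 0.773). Of 7 copper genes, 2 were higher and 4 lower (2 and 4 adjusted over the list alone), with the transporter gene CTR3 at -1.53 ± 0.12 and the metallothionein gene CRS5 at 0.92 ± 0.16. Scaling to the same spread left 1 higher and 2 lower, and quantile normalization 1 and 1. The lists of phosphate, iron, zinc and copper genes did not pass (adjusted p = 0.886, 0.203, 0.221 and 0.953).

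Purine genes were lower for 6 of 15 (6 adjusted over the list alone), with MTD1 at -0.94 ± 0.09 and ADE1 at -0.67 ± 0.08, at an adjusted p = 0.0281 and adjusted p = 0.167 with an estimated correlation. Thiamine genes were higher for 5 and lower for 3 of 19 (5 and 3 adjusted over the list alone), with no shift (adjusted p = 0.651). Seripauperin and mannoprotein genes were lower for 15 of 26 (15 adjusted over the list alone), with TIR1 at -1.41 ± 0.14, at an adjusted p = 0.00063 and adjusted p = 0.285 with an estimated correlation. Aryl-alcohol dehydrogenase genes were higher for 4 of 5 (4 adjusted over the list alone), with AAD14 at 1.25 ± 0.08, at an adjusted p = 0.00149 and adjusted p = 0.194 with an estimated correlation. Flocculin genes were lower for 3 of 6 (3 adjusted over the list alone), with FLO9 at -0.80 ± 0.15. FLO11 was at -0.51 ± 0.24 and not called, but was called without wild strain culture 2 (-0.71, adjusted p = 0.00735), with a replicate block (-0.51, 0.0465), with a random block (-0.53, 0.0489), with array weights (-1.04, 0.000233) and in cultures A to C (-0.94, 0.00216). Of 17 meiosis genes, 1 was higher and 7 lower (1 and 7 adjusted over the list alone), with IME1 at -0.96 ± 0.18, and the list did not pass (adjusted p = 0.554). Of 12 COS genes, 2 were higher and 1 lower (2 and 1 adjusted over the list alone), with COS111 at 0.85 ± 0.14 (list adjusted p = 0.953). Counts of some of these lists also changed with scaling: quantile normalization left 1 higher and 3 lower for purine, 2 higher and 2 lower for thiamine, 1 lower for flocculin and 4 lower for meiosis genes. CRS5 and COS111 were not called in cultures 1 to 3 alone (0.63 and 0.77, adjusted p = 0.0973 and 0.0661), nor FLO9 in channel 2 alone (-0.60, 0.0602). None of 8 core histone genes was called by limma (0 adjusted over the list alone), and HTB1 was at 0.23 ± 0.12 (adjusted p = 0.122), or called without wild strain culture 2 (0.31, adjusted p = 0.0228), with array weights (0.47, 0.000605) and in cultures A to C (0.41, 0.0108).

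Of 74 genes outside the Ty elements with a fall of 4-fold or more, among 5377, 18 adjacent pairs both fell, against a median of 1 and a highest value of 7 in 10000 random placements (permutation p = 0.0001, the smallest they can give). Of these, 17 lay among the 10 outermost genes of a chromosome end or in repeated families such as ENA and ASP3, where signal shared between copies may add pairs, which was not tested. Outside these, 1 pair was left, LIF1 with MF(ALPHA)2, named after their values were seen, against a median of 0 and a highest value of 3 (permutation p = 0.153), so whether neighbouring genes fall together beyond them is left open. Among the 10 outermost annotated genes of each chromosome end, 39.1% of 271 tested genes were lower in the wild strain, against 18.6% of 5106 others (permutation p = 0.0001, the smallest they can give). Without the Y' helicases it was 37.5% of 264, with other reading frames of the Y' element left in, and near-identical copies are not independent. Among genes with a standard name outside repeated families, 27.3% of 161 were lower at the ends, against 18.0% of 4767 others (permutation p = 0.0034), and as many were higher at the ends, 27.3%, so a tendency to falls is left open. Segments absent from the wild strain, or sequence that differs from the probes, may give such falls as well as lower transcription; these cannot be separated by ratios alone and were not tested. By another hypothesis, pathway genes are higher in the strain that lacks one of their enzymes. Called leucine genes (9 higher, 0 lower in the wild strain) and pyrimidine genes (4 higher, 2 lower) mostly went that way. It was not borne out for lysine, where 5 called genes were higher in the wild strain and BY4716 lacks LYS2. The lysine shift was itself not firm (camera adjusted p = 0.518 with an estimated correlation), so this does not decide the hypothesis.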
